A study of Homo sapiens with 6 samples.

How the data were processed

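Total RNA from cultures of HOS, an established human osteosarcoma cell line grown in MEM with fetal bovine serum, was measured on 6 one-colour Affymetrix PrimeView arrays with biotin-labelled cRNA. The sample titles give 3 control and 3 treated arrays and name each array a biological replicate. Other labels give the exposure as fluoride at 8 mg per litre for 30 days. The labels attach the same treatment text to every array, so the group was taken from the titles and the exposure label. Whether the cultures of a group were kept apart during the 30 days is not stated, so the p-values measure the spread between these samples only.

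The authors deposited log2 expression values, 1 column per array, made with RMA in Affymetrix Expression Console per the submitters' processing notes. RMA corrects background, normalizes between arrays by quantiles and summarizes the probes of a probe set; the version, any filter and the genome build are not given in the sources used here. The deposited log2 values ran from 1.69 to 14.1, and the per-array medians over all probe sets from 4.14 to 4.20. No value is centred per gene. Arrays give no read depth, so the number of arrays limits the precision; the median standard error of a log2 fold change was 0.0989.

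The table held 49395 probe sets, of which 102 were Affymetrix control probe sets. Names came from GEO's platform annotation through a probe table, which can be old. Of the other 49293 probe sets, 44988 had exactly 1 gene symbol, 1832 had several and 2473 were not listed there; no gene was named from the last 2 kinds. Gene identifiers were matched to a RefSeq gene table of assembly GRCh38.p14, which renamed 0 symbols and placed 13174 of the 13181 tested genes (99.9%) on a chromosome. That table served for names, gene span, neighbours and local gene density only. No coordinates are printed, because the build behind the files is not given in the sources used here. Some genes of the lists are not analysed here.

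For each of 18132 symbols the probe set with the highest mean over all 6 arrays was kept. Probe sets with a mean under the 40th percentile of all probe sets (log2 3.60) were left out, since the values carry no detection call. This left 13181 genes, of which 7046 had more than 1 probe set above the filter. Fluoride was compared with control by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group only, two-sided, Benjamini-Hochberg adjusted p under 0.05). Log2 fold changes are fluoride minus control and are followed by their standard error (SE), with 3 arrays in each group. A fold change on RMA values understates changes of dim probe sets, and probe sets whose names carry x or s can bind related transcripts, which matters for HLA, SAA, IFITM, metallothionein and ribosomal protein genes.

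The 34 gene lists, fixed with the groups, tests, naming rule and alternatives before the data were examined, were tested by camera with a preset inter-gene correlation of 0.01 and again with an estimated correlation; at least 5 tested members were required. Chromosomes and windows of 20 Mb with at least 20 tested genes were tested in the same way. Genes were named by rule: the 12 largest rises and 12 largest falls past the threshold whose groups did not overlap, up to 4 members with the smallest p in every list, and RUNX2, ALPL, COL1A1, SPARC and EZH2 in any case. Gene density is the number of protein-coding genes within a 1 Mb window. Probe sequences were not used here, so no correction for probe GC content was run, and gene density and span stood in for it. Whether control and fluoride arrays were hybridised and scanned together is not given in the sources used here.

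Alternatives covered the dim filter, centring, quantile normalization applied again, cyclic loess, the mean of a gene's probe sets, each probe set by itself, a trended and robust prior, array weights, the replicate number as a block, each array left out in turn, an unmoderated test, other thresholds, fry and rank-based camera. One further setting, chosen after seeing the data, removed from each array its trend with gene span, local gene density and mean expression, using splines of 4 degrees of freedom. The procedure was tested on simulated data for fluoride against control with 13181 genes, 200 of them changed. It recovered 1.49% of the changes of 0.3 log2 units, 59.7% of those of 0.6 and 83.3% of those of 1. Unchanged genes made up 4% of the calls, and unchanged data gave 0 calls. The simulated genes varied independently, without any shift shared between genes of an array, so these rates need not hold for the real arrays. In a simulation with a planted trend with gene density, 3388 calls fell to 100 after its removal. The planted trend was linear in the same log2 density that the removal fits, so this drop was built in. It does not show how well a trend of another form would be removed. No trend with gene span was planted.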

Results

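Gene expression was measured in HOS cells, an osteoblast-like human osteosarcoma line, to ask how prolonged exposure to fluoride, an ion that accumulates in bone, changed the transcriptome. The arrays comprised 3 of untreated cells and 3 of cells held in fluoride at 8 mg per litre for 30 days, and 13181 genes were tested. The labels used here name no time in culture for the control arrays. A difference in time in culture therefore cannot be told apart from an effect of fluoride. Pearson correlations of the 6 arrays averaged 0.994 within the control group and 0.996 within the fluoride group, and no pair of arrays held the same values.

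The largest rises with fluoride were those of PLAAT4, a retinoid-inducible phospholipase and acyltransferase on chromosome 11 (2.18-fold; log2 fold change 1.12 ± 0.12 SE, 3 arrays per group), and SAA1, an acute-phase protein also on chromosome 11 (2.12-fold; 1.08 ± 0.12). Complement component C3 rose by 0.98 ± 0.20 on the log2 scale, from 3.99 ± 0.16 in control to 4.97 ± 0.46 in fluoride (mean ± SD, n = 3 each). IFITM1, an interferon-induced membrane protein, rose 1.67-fold, and the chemokine gene CCL2 rose 1.54-fold. PLAU, which encodes urokinase, and FBXO32, a muscle-atrophy ubiquitin ligase, each rose 1.57-fold. The remaining genes among the 12 largest rises were ORAI3, a store-operated calcium channel subunit, SLC12A8, EML2, the retinaldehyde reductase gene DHRS3 and COX7A1, with log2 fold changes from 0.60 to 0.63. All 12 had adjusted p-values of 0.0142 or less in limma. EML2 was higher in 2 of its 3 probe sets above the filter, and the mean of its probe sets did not pass (adjusted p = 0.107). COX7A1 did not pass without fluoride replicate 3 (adjusted p = 0.0545). ORAI3 rose by 0.40 with the trend with gene span and density removed, and SLC12A8 by 0.40 with the mean of its probe sets.

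Falls were larger than rises. The gene with the largest fall was DLEU2, a long non-coding RNA on chromosome 13 that hosts a microRNA cluster (log2 fold change −1.39 ± 0.29; 2.62-fold lower). CHORDC1, a co-chaperone of HSP90, fell from 7.70 ± 0.35 in control to 6.32 ± 0.10 in fluoride (mean ± SD, n = 3 each), 2.59-fold. The small Cajal body RNA SCARNA14 (−1.33 ± 0.26), the UDP-N-acetylglucosamine enzyme UAP1 (−1.31 ± 0.20) and the mitochondrial folate carrier SLC25A32 (−1.25 ± 0.10) followed. OSBPL11, a lipid-binding protein, the kinase-anchoring scaffold AKAP12, the ubiquitin ligase CBLL1, the homeobox gene SIX4 and CAND1, an exchange factor of cullin ligases, had log2 fold changes from −1.24 to −1.21. DTL, a substrate receptor of a cullin ligase active in S phase (−1.18 ± 0.13), and the nuclear export receptor CSE1L (−1.15 ± 0.13) completed the 12 largest falls. Their adjusted p-values were 0.00869 or less in limma, and all 3 fluoride values lay below all 3 control values for each of these 12 genes. With the mean of its probe sets CAND1 fell by 0.75.

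**Figure D1:**
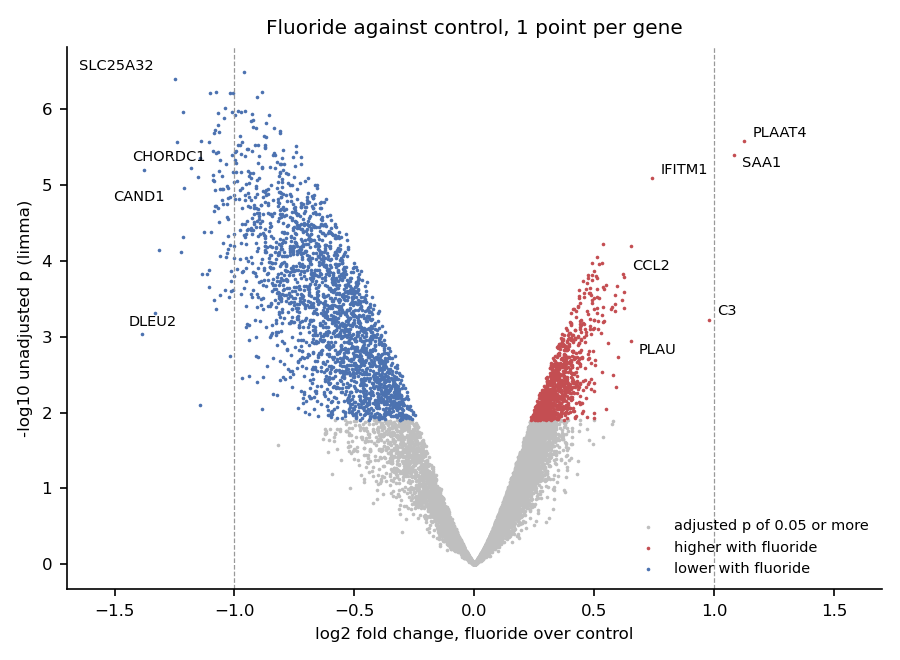
Each point is 1 of the 13181 tested genes, with the log2 fold change (fluoride over control) on the x axis and −log10 of limma's unadjusted p on the y axis; red and blue mark genes past an adjusted p of 0.05, and dashed lines mark 2-fold changes. The 989 higher genes lie mostly close to 0 (median 0.34), and the 2290 lower genes reach further out (median −0.59).

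**Figure D2:**
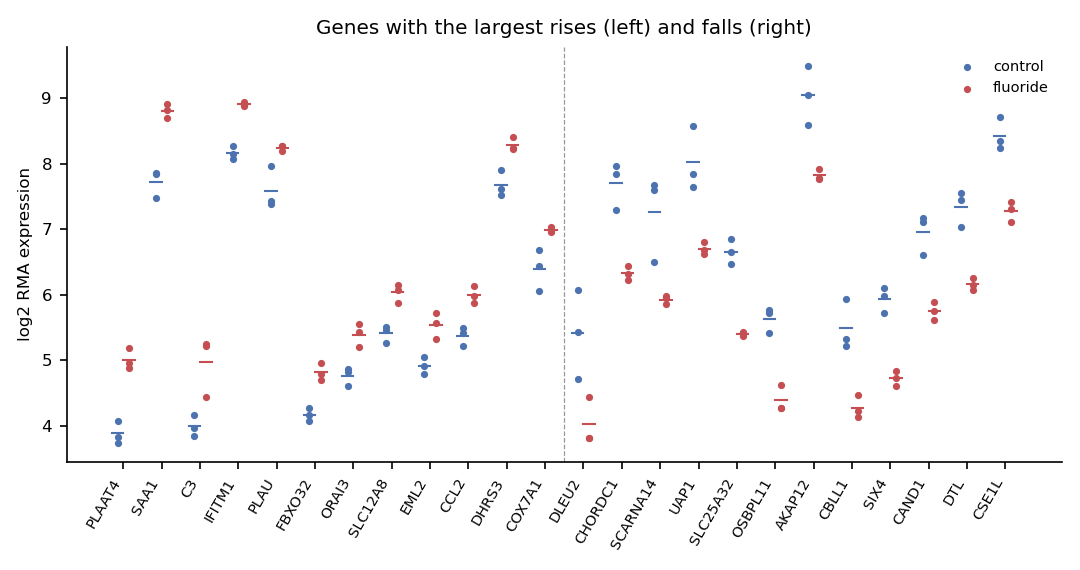
Log2 RMA expression of the 12 genes with the largest rises (left of the dashed line) and the 12 with the largest falls (right), with 1 point per array (blue, control; red, fluoride; 3 each) and short bars at the group means. The groups do not overlap for any of these genes, and the control arrays of DLEU2 spread widely (SD 0.68).

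In all, 3279 genes (24.9% of those tested) differed at an adjusted p under 0.05 in limma, 989 higher and 2290 lower with fluoride. Of these, 89 changed at least 2-fold. PLAAT4 and SAA1 were the 2 that rose, and 87 fell. Over all tested genes, called or not, 8198 lay above 0 and 4983 under 0, with a median log2 fold change of 0.07. The 3 values of one group lay wholly on one side of the other group's for 6081 genes (46.1%, where chance gives 10%). Quantile normalization applied again gave 2005 higher and 2136 lower genes (51.6% lower, against 69.8% in the main comparison), cyclic loess 79.7% lower, and removal of the trend with gene span and density, a setting chosen after seeing the data, 1579 higher and 1575 lower (49.9%). The count fell to 1809 (86.0% lower) without fluoride replicate 3, the share lower was 81.3% without control replicate 1 and 80.8% without fluoride replicate 1, and the 2-fold count was 48 without control replicate 1, 139 without fluoride replicate 1 and 196 without control replicate 3.

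Of 32 tested mitosis and G2/M genes, 16 were lower and 0 higher (17 lower when adjusted over the list alone), with a list median of −0.37 and 6 members above 0. They included cyclin A2 (CCNA2, −0.84 ± 0.09), the kinetochore gene NDC80 (−0.75 ± 0.09), topoisomerase TOP2A (−0.69 ± 0.09) and the spindle gene DLGAP5 (−0.85 ± 0.12). Of 35 DNA replication and S-phase genes, 13 were lower and 0 higher, the same number adjusted over the list alone, and 11 members lay above 0. The lower genes included the polymerase subunit POLE2 (−0.80 ± 0.10), the clamp loader subunit RFC3 (−0.74 ± 0.10), the ribonucleotide reductase subunit RRM1 (−0.92 ± 0.13) and the primase PRIM1 (−0.79 ± 0.11). Camera placed both lists below the other genes (adjusted p = 1.01e-05 for mitosis and 0.00394 for replication). With an estimated correlation the adjusted p was 0.283 for mitosis and 0.368 for replication, and neither call held. With the span and density trend removed the mitosis median was −0.18 (adjusted p = 2.63e-04; 0.504 with an estimated correlation) and the replication list did not pass (adjusted p = 0.146). NDC80 then fell by 0.45 and RFC3 by 0.49.

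Some interferon-stimulated, antigen presentation and cytokine genes were higher. Of 24 interferon-stimulated genes, 7 were higher and 0 lower (7 adjusted over the list alone), among them IFITM1 (0.74 ± 0.09), the transcription factor IRF9 (0.53 ± 0.08), IFI6 (0.42 ± 0.08) and the exonuclease ISG20 (0.50 ± 0.10). Of 17 antigen presentation genes, 7 were higher and 0 lower (8 adjusted over the list alone), including the immunoproteasome subunits PSMB9 (0.47 ± 0.08) and PSMB8 (0.38 ± 0.10) and the peptide-loading factor TAPBP (0.42 ± 0.09; 0.27 with the mean of its probe sets). PSMB8 did not pass without fluoride replicate 2 (adjusted p = 0.0602) or fluoride replicate 3 (adjusted p = 0.0611), or with the span and density trend removed (adjusted p = 0.0715). Of 23 NF-kB targets, cytokines and chemokines, 5 were higher and 1 lower (8 higher and 2 lower adjusted over the list alone). CCL2 was higher in each fit with 1 array left out. TNF (0.35 ± 0.09) did not pass without control replicate 1, control replicate 3, fluoride replicate 2 or fluoride replicate 3, with adjusted p-values from 0.0507 to 0.0853, or with the trend removed (0.19, adjusted p = 0.119). The lower member was TNFAIP3, a feedback inhibitor of NF-kB (−0.34 ± 0.10), which did not pass without control replicate 1 (adjusted p = 0.0838), fluoride replicate 2 (adjusted p = 0.0940) or fluoride replicate 3 (adjusted p = 0.109), with the mean of its probe sets (−0.21, adjusted p = 0.0727) or with the trend removed (−0.13, adjusted p = 0.334). Of 6 immune cell markers above the filter, 3 were higher (5 adjusted over the list alone). CD14 rose by 0.48 ± 0.08 from a dim control level of 4.01 and did not pass with the trend removed (adjusted p = 0.0979). The list medians were 0.21 for interferon-stimulated genes, 0.21 for antigen presentation, 0.21 for the NF-kB list and 0.28 for immune cell markers. The median over all tested genes was 0.07.

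Camera placed these 4 lists above the other genes, with adjusted p-values of 0.00394 for interferon-stimulated genes, 0.00394 for antigen presentation, 0.0334 for the NF-kB list and 0.0264 for immune cell markers. With an estimated correlation the adjusted p was 0.283 for each of the 4, and no call held. Without control replicate 3 the NF-kB list (adjusted p = 0.0545) and the immune cell markers (adjusted p = 0.0612) did not pass, and the NF-kB list did not pass without fluoride replicate 1 (adjusted p = 0.0615) or fluoride replicate 2 (adjusted p = 0.0539), with the stricter dim filter (adjusted p = 0.0728) or with array weights (adjusted p = 0.0506) either. With the span and density trend removed, interferon-stimulated genes passed (adjusted p = 0.0382; 0.504 with an estimated correlation) while antigen presentation (adjusted p = 0.202), the NF-kB list (adjusted p = 0.187) and immune cell markers (adjusted p = 0.389) did not. The members of the antigen presentation and immune lists lie in gene-dense regions, with a median of 34 and 39.5 genes per 1 Mb window against 14 for all tested genes, and GC-rich background probe sets were brighter by 0.22 log2 units on the fluoride arrays.

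Of 22 genes of the endoplasmic reticulum stress response, 8 were lower, 0 higher and 14 did not pass (9 lower adjusted over the list alone). The lower genes included the co-chaperones DNAJB9 (−0.93 ± 0.10) and DNAJB11 (−0.65 ± 0.09), the HSP90 homologue HSP90B1 (−0.62 ± 0.09) and calnexin (CANX, −0.57 ± 0.10). The list passed camera at an adjusted p of 0.0334 (median −0.11), and its adjusted p was 0.406 with an estimated correlation. It did not pass without control replicate 3 (adjusted p = 0.0871) or fluoride replicate 1 (adjusted p = 0.0934), with the stricter dim filter (adjusted p = 0.179), with quantile normalization again (adjusted p = 0.0503), with cyclic loess (adjusted p = 0.0759), with the mean of probe sets (adjusted p = 0.131) or with the trend removed (adjusted p = 0.146). Other stress lists did not pass. Of 24 heat shock and metallothionein genes, 6 were lower, including HSPH1 (−0.99 ± 0.09), HSPD1 (−0.64 ± 0.08), the zinc transporter SLC30A1 (−0.69 ± 0.11) and DNAJA1 (−0.71 ± 0.12), and 3 were higher (camera adjusted p = 0.551). Of 27 NRF2 targets and antioxidant enzymes, 6 were lower and 1 higher (adjusted p = 0.605), with falls of thioredoxin reductase TXNRD1 (−0.66 ± 0.09), the glutathione synthesis enzyme GCLC (−0.64 ± 0.09; −0.41 with the mean of its probe sets) and peroxiredoxin PRDX3 (−0.60 ± 0.08). ATF4 targets went both ways, with 4 of 26 higher, including DDIT4 (0.51 ± 0.08) and NUPR1 (0.43 ± 0.08; 0.29 with the trend removed), and 2 lower, including MTHFD2 (−0.42 ± 0.09; list adjusted p = 0.605). Among 22 p53 targets and apoptosis genes, 3 were higher and 3 lower (adjusted p = 0.804), with DDB2 at 0.49 ± 0.09 and PMAIP1 at −0.72 ± 0.10.

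Chromatin and DNA repair genes that passed were mostly lower, as were 69.8% of all called genes. EZH2, the histone methyltransferase of Polycomb repressive complex 2, fell from 6.08 ± 0.05 to 5.70 ± 0.08 (mean ± SD, n = 3 each; log2 fold change −0.37 ± 0.08 SE, adjusted p = 0.0108), and with the trend removed it did not pass (−0.21, adjusted p = 0.0904). It was 1 of 11 lower genes among 42 DNA and histone methylation enzymes, of which 0 were higher. SUZ12, a partner of EZH2 in that complex (−0.68 ± 0.11), the methyltransferase SUV39H2 (−0.72 ± 0.10) and the demethylase KDM3A (−0.58 ± 0.10) also fell. The list did not pass (camera adjusted p = 0.0641), nor did 26 DNA repair genes (adjusted p = 0.0697), of which 9 were lower, including MSH6 (−0.91 ± 0.13), PRKDC (−0.80 ± 0.12; −0.49 with the trend removed) and BLM (−0.59 ± 0.12). Of 26 histone acetylation enzymes, 7 were lower, including the deacetylases HDAC2 (−0.94 ± 0.11; −0.62 with the trend removed) and SIRT1 (−0.82 ± 0.10), and 3 were higher (adjusted p = 0.763).

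Osteoblast genes moved in both directions in the main comparison. RUNX2, the master transcription factor of osteoblasts, was lower (−0.39 ± 0.12, adjusted p = 0.0351), but did not pass without control replicate 1 (adjusted p = 0.0923), control replicate 3 (adjusted p = 0.0619), fluoride replicate 2 (adjusted p = 0.105) or fluoride replicate 3 (adjusted p = 0.102), or with the trend removed (adjusted p = 0.126). SP7, which encodes osterix, was higher (0.40 ± 0.08, adjusted p = 0.00719), from a dim control level of 3.93, and did not pass with the trend removed (adjusted p = 0.108). Alkaline phosphatase (ALPL, 0.27 ± 0.09, adjusted p = 0.0579), type I collagen (COL1A1, 0.23 ± 0.11, adjusted p = 0.132) and osteonectin (SPARC, 0.08 ± 0.10, adjusted p = 0.566) did not pass. ALPL passed with quantile normalization again (adjusted p = 0.0172) and with the trend removed (0.51, adjusted p = 0.00643), and COL1A1 passed with quantile normalization again (adjusted p = 0.0353). Of 16 osteoblast and bone matrix genes above the filter, 2 were higher and 2 lower (camera adjusted p = 0.201). With the trend removed 1 was higher and 0 lower. The other called members, BGLAP (limma adjusted p = 0.128) and ANKH (limma adjusted p = 0.440), did not pass then either.

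Matrix, adhesion and signalling genes showed mixed changes. Of 34 collagens and other extracellular matrix genes, 8 were higher and 8 lower (adjusted p = 0.763), with thrombospondin THBS1 at −0.90 ± 0.10 although 2 of its 4 probe sets above the filter did not share that direction (mean of its probe sets −0.34). With the trend removed 13 were higher and 2 lower and the list passed (adjusted p = 0.0132; 0.504 with an estimated correlation). Of 23 matrix proteases and inhibitors, 6 were higher, including MMP2 (0.46 ± 0.10; 0.71 with the trend removed) and PLAU, and 3 lower, including ADAMTS1 (−0.53 ± 0.09; list adjusted p = 0.317). Integrin subunits ITGA6 (−0.69 ± 0.08; −0.39 with the trend removed) and ITGA4 (−0.62 ± 0.09) were among 7 lower genes of 21 in the adhesion list, against 2 higher (adjusted p = 0.763). The balance turned over with the trend removed, to 7 higher and 3 lower. Of 22 TGF-beta and YAP targets, 7 were lower, including the receptor TGFBR1 (−0.95 ± 0.15) and the kinase LATS2 (−0.55 ± 0.09; −0.33 with the trend removed), and 0 higher (adjusted p = 0.0705). BMP pathway genes had 6 lower members of 18, including ID2 (−0.53 ± 0.09) and SMAD5 (−0.66 ± 0.12; −0.38 with the trend removed), and 1 higher (adjusted p = 0.605). Trend removal left 3 higher and 3 lower. Wnt genes had 6 lower members of 30, including the inhibitor DKK1 (−0.59 ± 0.10) and the receptor LRP6 (−0.66 ± 0.13), and 2 higher (adjusted p = 0.830). Here too the balance turned over with the trend removed, to 8 higher and 2 lower. Of 38 growth factor and immediate-early genes, SPRED1 (−0.87 ± 0.13) and SPRED2 (−0.87 ± 0.13), inhibitors of the Ras-MAPK pathway, were the 2 that fell, with 0 higher (adjusted p = 0.830). SPRED1 fell by 0.56 with the trend removed, and the list then had 5 higher and 2 lower members. Of the 2 probe sets of SPRED2 above the filter 1 lay lower, and with their mean it fell by 0.31 (adjusted p = 0.0418).

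The smooth muscle, epithelial, mesenchymal, chondrocyte and adipocyte lists did not pass camera. Among 14 smooth muscle and myofibroblast markers 3 were higher and 1 lower (CALD1, −1.05 ± 0.13; list adjusted p = 0.321). CALD1 was lower in 7 of its 9 probe sets above the filter, and fell by 0.38 with their mean. Epithelial markers had 3 higher and 2 lower members of 13, the latter CLDN1 (−0.73 ± 0.13) and EPCAM (−0.52 ± 0.11; list adjusted p = 0.557). Mesenchymal transition regulators had 3 higher and 3 lower of 13, with SNAI2 at −0.61 ± 0.10 (list adjusted p = 0.763). SOX9 was the 1 lower gene of 10 chondrocyte markers (−0.66 ± 0.18; list adjusted p = 0.763) and did not pass without fluoride replicate 1, 2 or 3 (adjusted p from 0.0502 to 0.0985), and its change was −0.42 without control replicate 1. Of 7 adipocyte markers 0 passed limma, and the 1 with an unadjusted p under 0.05 was CEBPA (0.25 ± 0.09, adjusted p = 0.0678; list adjusted p = 0.763).

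Metabolic and transport lists did not shift as lists, although single members fell. Among all 13181 tested genes 2290 were called lower, so a few lower members do not set a list apart. Of 40 nuclear-encoded oxidative phosphorylation genes 4 were lower and 0 higher, led by the succinate dehydrogenase subunit SDHD (−0.87 ± 0.08; −0.57 with the mean of its probe sets; list adjusted p = 0.605). That list had 3 higher and 2 lower members with the trend removed. Of 31 glycolysis and hypoxia genes 4 were higher, including ALDOC (0.51 ± 0.08) and PFKFB4 (0.51 ± 0.09; 0.30 with the mean of its probe sets), and 3 lower, including the prolyl hydroxylase EGLN1 (−0.88 ± 0.12; −0.33 with the mean of its probe sets; list adjusted p = 0.763). The 5 lower genes of 24 in fatty acid metabolism included ACADM (−0.69 ± 0.11; −0.40 with the trend removed; list adjusted p = 0.605), and 5 of 19 in cholesterol synthesis included MSMO1 (−0.55 ± 0.09; list adjusted p = 0.763), with 0 higher in both. After trend removal the fatty acid list had 3 higher and 3 lower members and the cholesterol list 3 higher and 2 lower. In the list of chloride, proton and other anion transport, 6 of 26 genes were lower, including the proton pump subunit ATP6V1A (−1.05 ± 0.12) and CLIC4 (−0.91 ± 0.12; −0.53 with the mean of its probe sets), and 1 was higher (adjusted p = 0.437). In calcium and phosphate handling, 6 of 29 were lower, including the calcium pump ATP2C1 (−0.95 ± 0.15) and the calcineurin subunit PPP3CA (−0.67 ± 0.09), and 4 were higher, including ORAI3 (adjusted p = 0.763). Of 40 cytosolic ribosomal protein genes, 1 was lower, RPL7 (−0.58 ± 0.15), and 0 were higher (list adjusted p = 0.676). RPL7 did not pass without control replicate 1 (adjusted p = 0.0540), fluoride replicate 2 (adjusted p = 0.0595) or fluoride replicate 3 (adjusted p = 0.0796), or with the trend removed (adjusted p = 0.0548).

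**Figure D3:**
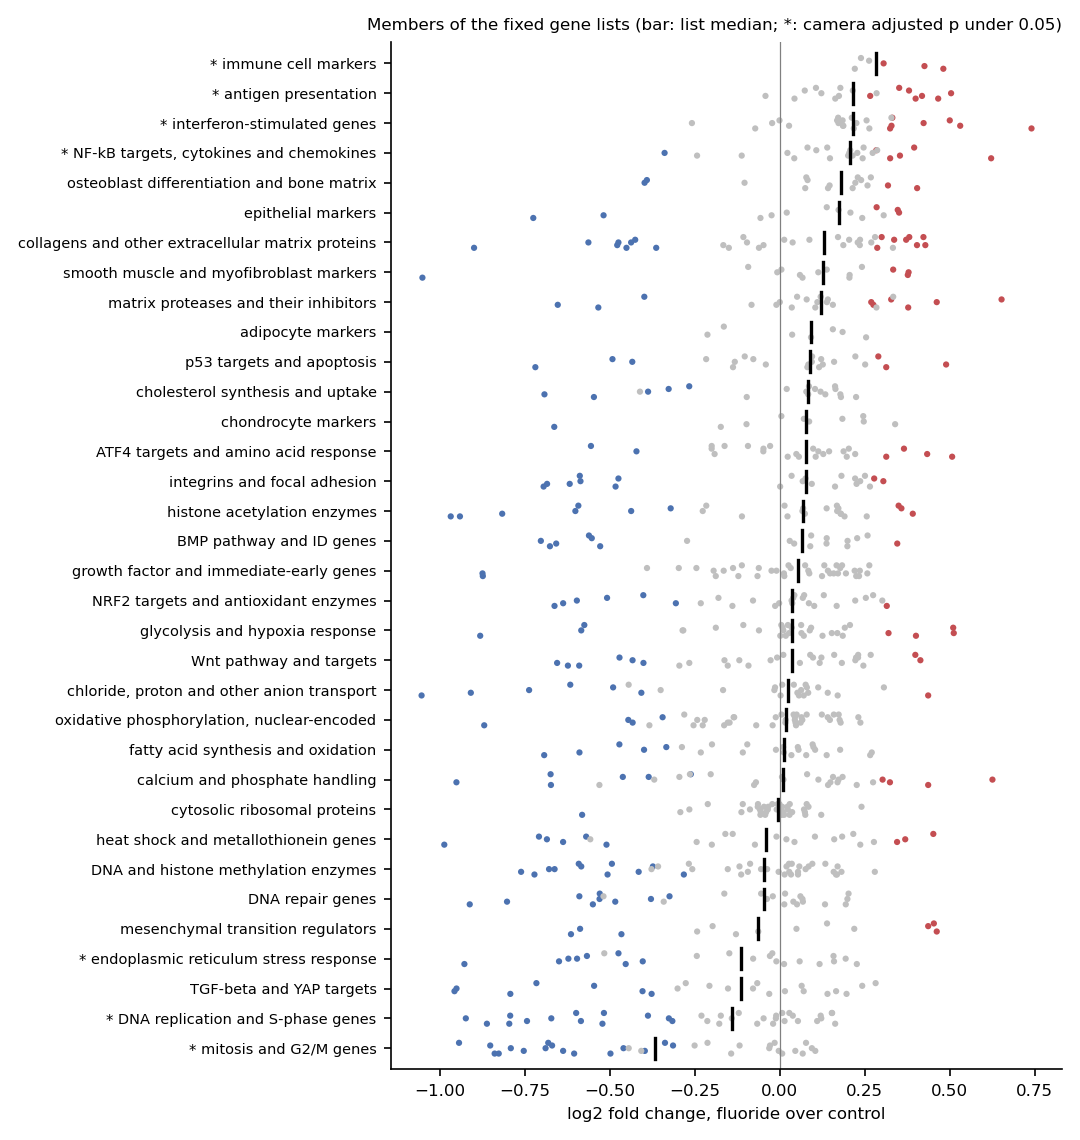
Log2 fold changes (fluoride over control, x axis) of the tested members of the 34 gene lists, with 1 point per gene (red, higher and blue, lower at an adjusted p under 0.05; grey, not past it), a black bar at each list's median and an asterisk at the 7 lists past camera's threshold. The mitosis and G2/M list has the lowest median (−0.37) and the immune cell markers the highest (0.28).

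Over the 34 lists, 7 passed camera with the preset correlation, 4 higher and 3 lower, and 4 passed without control replicate 3. With an estimated correlation 0 passed (lowest adjusted p 0.283; 5 at an unadjusted p under 0.05), and fry, which asks whether the members of a list move one way and does not compare them with other genes, called 16. Adjusted over the list alone, counts differed in 14 of the 27 lists that did not pass, such as 11 higher collagens and matrix genes in place of 8, 5 higher adhesion genes in place of 2, 3 higher NRF2 targets in place of 1, and 0 lower chondrocyte and ribosomal genes in place of 1. Median and mean differed in sign for 11 lists, where a few large falls stood against small rises. In the chloride, oxidative phosphorylation, fatty acid, BMP, NRF2, calcium, histone acetylation, cholesterol, integrin and Wnt lists the median lay above 0 and the mean and test below; in the growth factor list the median and test lay above 0 and the mean below.

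The change differed between chromosomes. Of 23 chromosomes, 11 passed camera. Camera placed chromosomes 13, 4, 18, 5, 2, 8 and 3 below the other genes. The medians of chromosomes 2, 8 and 3 were not below 0 (0.01, 0.00 and 0.01), but lay under the 0.07 of all tested genes. The lowest median was that of chromosome 13 (−0.22 over 200 genes, of which 37% were called lower), the chromosome of DLEU2, RFC3 and HSPH1. Chromosomes 19, 22, 16 and 17 were placed above the other genes, with medians of 0.14 for chromosomes 19 and 22; on chromosome 19, which carries C3, 1.85% of 975 genes were lower and 11.3% higher. With an estimated correlation 5 calls held, those of chromosomes 13, 4, 5, 2 and 3, at adjusted p-values of 0.0353 or less. The chromosome median followed the median gene density over 23 chromosomes (Pearson r = 0.712, permutation p = 7e-04, and Spearman rho = 0.917, permutation p = 1e-05). The latter p is the smallest that 100000 permutations can give. Both p-values are unadjusted, and this relation was not among the tests fixed before the data were examined. Without the 2 chromosomes of most extreme density r was 0.769. Across genes, which are not independent replicates, the log2 fold change correlated with gene density (Spearman rho 0.368) and with gene span (−0.262). With genes cut into 4 equal groups by density, 33.3% of the sparsest group were lower and 1.86% of the densest. With the trend removed, chromosome 22 was the 1 that passed (median 0.13, adjusted p = 0.00149; 0.175 with an estimated correlation).

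**Figure D4:**
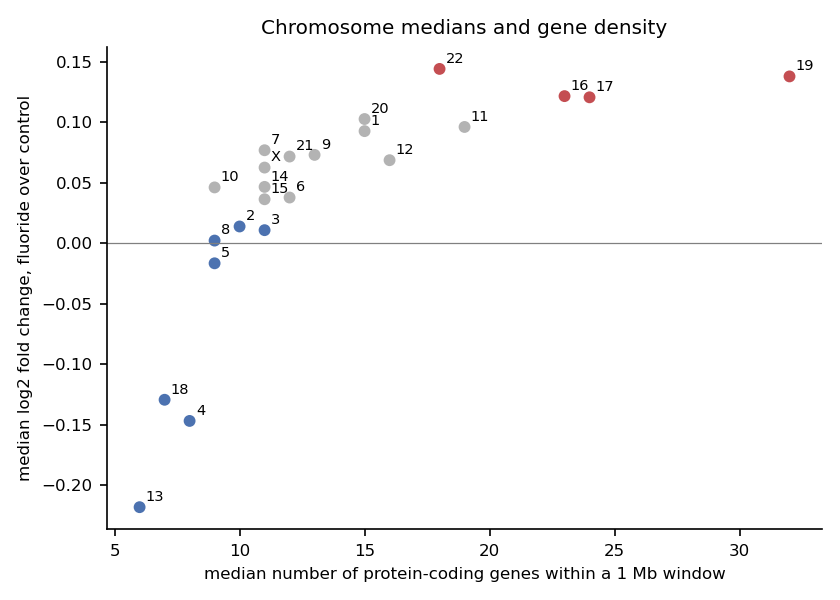
Median log2 fold change (fluoride over control, y axis) of the tested genes of each of 23 chromosomes against the median number of protein-coding genes within a 1 Mb window (x axis); red and blue mark chromosomes that camera placed above and below the other genes, and grey those not past the threshold. Gene-poor chromosomes 13, 4 and 18 lie lowest and gene-dense chromosomes 19 and 22 highest.

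The first principal component held 66.8% of the variance and separated the groups. Signals of RNA integrity overlapped between groups, with a 3' minus 5' difference for ACTB of 2.96 ± 0.03 in control and 2.97 ± 0.08 in fluoride (mean ± SD, n = 3 each), and for GAPDH of 0.745 ± 0.025 and 0.767 ± 0.033. Background control probe sets with 15 to 25 G or C bases averaged 5.59 ± 0.01 in control and 5.82 ± 0.06 in fluoride, higher by 0.22 (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 allows). Control replicate 2 had brighter poly-A spike-ins (7.65, against 6.67 to 7.03 on the other arrays) and dimmer hybridization spike-ins (10.1, against 10.5 to 10.7).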

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

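The tests of RNA degradation, of the gene count under other splits of the arrays, of the background gain and of immune cells were chosen only after the results they bear on were seen, and so was the removal of the trend with gene span and density.

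Signals outside the comparisons also differed between the groups. Background control probe sets with 15 to 25 G or C bases, which match no human gene, were brighter on the fluoride arrays by 0.22 log2 units, and all 13 background sets with at least 13 G or C bases were brighter on every fluoride array than on any control array. Among 2390 probe sets with no gene symbol or several, 502 differed in limma, 133 higher and 369 lower, and 20 of the 22 that changed at least 2-fold fell. Groups of 3 arrays were too small for a test of single outlying arrays. Estimated array weights ran from 0.568 for control replicate 1 to 2.11 for fluoride replicate 3.

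The first pattern is that, among called genes, falls with fluoride were larger and more numerous than rises. Degraded RNA is argued against by 3' minus 5' differences that changed by 0.0220 log2 units or less, and misreporting by single probe sets by the further probe sets of 1473 fallen genes, which lay lower in 89.1%. A technical trend stays open, with no correction for probe GC content run here. The background slope with GC content differed by 0.0150 log2 units per base, with GC-rich background brighter in fluoride. The largest drop of a background probe set was 0.114 linear units, against a median loss of 37.2 among the fallen genes. That comparison decides nothing, because the set lay at log2 1.94 in control and had no such signal to lose. The 13 background sets with at least 13 G or C bases all rose in fluoride. Their rise argues against lost GC-rich background as the source of the falls, but not against other technical trends. With the trend with gene span and density removed, 64.4% of the fallen genes (1474 of 2290) were still lower. The excess of falls in number was then gone (1579 higher, 1575 lower), while at 2-fold 16 genes were lower and 0 higher, so falls stayed larger. That removal also took out a trend with mean expression and each array's mean offset, so the even counts are partly built in. Rescalings that use neither span nor density disagreed: 51.6% of called genes were lower with quantile normalization again, 77.5% with median centring and 79.7% with cyclic loess. The trend may account for part of the excess in number, although a response of long, isolated genes to fluoride cannot be told apart from it. The real split gave 3279 genes and the 9 other splits of the 6 arrays 0 (1 of 10 splits as large), for 2-fold changes 89 against 0, and 10 splits are too few for a share under 0.05. Each other split mixes control and fluoride arrays, so any difference between the groups lowers its count. The splits therefore cannot tell a fluoride effect from a technical difference.

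The second pattern is the rise of the interferon-stimulated and antigen presentation lists. HOS is an established cell line, so the design gives no source of immune cells in the fluoride cultures, and the arrays do not settle the point. PTPRC, a leukocyte transcript, changed by 0.0921 log2 units at the brightest of its 6 probe sets. It lay under the dim filter (mean 2.35, filter 3.60), which by itself decides nothing. All 6 tested immune markers lay above 0, with 3 called higher, and 0 were called with the trend with gene span and density removed. The trend with gene span and density stays open, because after its removal the interferon list passed with the preset correlation (adjusted p = 0.0382; 0.504 with an estimated correlation) and the antigen presentation list did not (adjusted p = 0.202). A GC-dependent background stays open too, since no correction for probe GC content was run. Of the 14 called members, 5 gained more linear signal than the largest gain of any background probe set (153). That comparison decides nothing, because linear gains grow with brightness. The background set, with 25 G or C bases, lay at log2 9.54 in control, against list means of 6.09 (interferon) and 7.97 (antigen presentation). On the log2 scale the largest background rise was 0.27, and the median of each list 0.21. A fluoride effect on these genes remains a hypothesis that these arrays do not separate from these.

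The third pattern is the fall of mitosis and G2/M genes. Membership in an abundance or span class alone is argued against by 10000 random lists matched on mean expression and gene span, whose median was 0.03. Of these, 0.01% had a median as low. That share is no p-value for the mitosis list, because the random genes were drawn independently while members of a list can move together. The random lists were not matched on gene density. The trend with span and density stays open in part: its removal took the list's median from −0.37 to −0.18, with the list still past the threshold (adjusted p = 2.63e-04; 0.504 with an estimated correlation). Slower proliferation in fluoride is a candidate explanation that was not tested, since the cultures' growth was not measured here. Over all lists the real split gave 7 calls and the highest of the other splits 6, and for chromosomes 11 against 6 (1 of 10 splits as large for each). As above, 10 splits are too few for a share under 0.05, and the other splits mix the groups.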

How the results depend on the processing

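Removal of the trend with gene span and density was chosen after seeing the data; the other settings were planned. No gene list or named gene past the threshold reversed direction in the settings that gave it a value; single probe sets of a gene were not compared in this way. The 3279 genes became 6453 with every probe set by itself, where 29576 probe sets were tested, and 651 with an unmoderated test, which does not share the spread between genes; leaving out 1 array gave 1809 to 2873. The 89 genes at 2-fold became 47 with quantile normalization again, 48 with the mean of probe sets, 226 with every probe set by itself, 1174 at 1.5-fold and 16 with the trend removed, and 48 to 196 with 1 array left out. The 7 lists became 0 with an estimated correlation, 16 with fry and 3 with the trend removed, and 4 to 9 with 1 array left out. The 11 chromosomes became 5 with an estimated correlation and 1 with the trend removed, and 10 or 11 with 1 array left out. Apart from the smaller samples, the changed null hypothesis of fry and the looser fold threshold, the cause was not tested. Of the 3277 called genes with a position, 2015 were called in the same direction with the trend removed.

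The replicate numbers did not pair the samples: deviations from the group means correlated at −0.0897, −0.235 and 0.0112 between arrays of the same number. With the replicate block 2566 genes passed, 502 higher and 2064 lower (80.4% lower), 2506 of them among the 3279 and in the same direction. Over all settings the named genes lost a call in 143 instances, gained one in 36 and kept their side of the threshold in 2331, and the lists in 24, 20 and 601. Signal over background limits the dim genes: C3, PLAAT4, SP7 and CD14 had control means near 4 log2 units, against a filter of 3.60.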

Other observations

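Falls were also uneven along chromosomes. Of 150 windows of 20 Mb, 76 passed camera with the preset correlation, 22 above and 54 below the other genes, and 0 with an estimated correlation (52 at an unadjusted p under 0.05). The window with the smallest p held 40 tested genes between UBE2E3 and MAIP1 on chromosome 2 (median −0.54, adjusted p = 9.28e-12; 0.124 with an estimated correlation), and the 33 genes between SMC4 and USP13 on chromosome 3 had a median of −0.56 (adjusted p = 2e-06; 0.139 with an estimated correlation). With the span and density trend removed, 21 windows passed, 8 above and 13 below, and 0 with an estimated correlation (21 at an unadjusted p under 0.05). The chromosome 2 window then had a median of −0.35 (adjusted p = 1.74e-06; 0.309 with an estimated correlation) and the chromosome 3 window −0.38 (adjusted p = 5.18e-04; 0.337 with an estimated correlation). These windows were singled out after their values were seen, and copy number was not measured here.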
